A study of Mus musculus with 8 samples.

How the data were processed

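RNA was measured in 6 libraries, 3 of cells given DMSO and 3 given C28 for 3 h, and H3K27ac in 2 libraries, 1 control and 1 C28, all from mouse cells labelled female germline stem cells. Groups and replicate numbers came from the sample titles. Per the labels' protocols, mRNA was isolated from total RNA and sequenced as read pairs, and 2 RNA library kits are named, 1 of which marks strand; which kit made these libraries, and whether counting used strand, are not given in the sources used here, so reads of overlapping antisense genes may not be told apart. Per the submitters' processing notes the genome build was mm9 and the tools Bowtie2 and Cufflinks 2.2.1, with no role given for either; the counting tool, the peak caller and the settings are not given in the sources used here.

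The deposited expression table holds 54232 Ensembl gene rows with values on a signal scale, made by the authors by dividing gene read counts by 1 size factor per library. This follows from the values: 100% of them are whole multiples, within 0.01, of the value of 1 read in their library, which lay between 0.935 and 1.07. Dividing by the value of 1 read gave 19197376, 18871411 and 18613916 reads for DMSO replicates 1 to 3 and 17167146, 16930212 and 17428321 for C28 replicates 1 to 3. The table also carries the authors' log2 fold change and the authors' adjusted p-value for C28 against DMSO. DESeq2 with a fold change prior and no block, run on the recovered reads, gave log2 fold changes within 0.00176 of the deposited ones and 184 calls, so the deposited fold changes are shrunken. The deposited peak lists hold, per peak, a score, a fold enrichment, −log10 p and −log10 q values from the authors' peak caller, 1 list per library; the lowest -log10 q was 2.02 and 2.03, and the score is 10 times -log10 q rounded down. Peak values are the authors' and were used to describe, rank or filter peaks within a list. Their medians, and counts past a common -log10 q cut, are also given side by side for both lists, with no correction for read depth.

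Gene names came from the table for 24187 rows and from a table of Ensembl identifiers for 29950 more, and 54079 of the 54232 identifiers matched that table. Mitochondrial genes carry names without the mt prefix in the table, and Emr1 was matched to Adgre1. Where a name had several rows, the row with the highest mean was kept. The design planned edgeR for counts and limma for a normalized unit; since the values are normalized, limma was the main test. Genes with a value of at least 1 in at least 3 of 6 libraries (19054) were tested with limma 3.58.1 in R 4.3.3, with an intensity trend in the prior variance, on log2(value + 1), and p-values were adjusted by Benjamini and Hochberg with a threshold of 0.05. Fold changes are on that log2(value + 1) scale, which understates the change of low genes. Group means and SD are of normalized counts over 3 libraries.

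The replicate numbers were checked for pairing before the fits were compared. Over 10572 genes averaging at least 50 normalized counts, deviations from the group means were correlated between same-numbered libraries. The correlation was 0.84 for replicate 1, 0.68 for replicate 2 and 0.71 for replicate 3, and each library correlated best with its own number. The numbers were therefore taken as pairs from the data, since no label states a pairing. Replicate 1 stood apart in both arms, which alone raises the correlations of replicates 2 and 3. How far 2 and 3 each preferred their own number is not given, so their pairing is less certain. With replicate 1 left out of both arms, limma called 91 genes without a replicate block and 853 with it. These counts go with a pairing of 2 and 3 but are no direct test of it. A fit with the replicate number as a block is given beside each result that it changed. No pair of libraries in a group agreed within counting noise. Between replicates 2 and 3 the chi-square per gene was 6.49 with DMSO and 5.72 with C28. Between replicate 1 and either of these it was 26.7 to 32.9, so replicates 2 and 3 were much more alike.

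Lists fixed before the data were examined covered autophagy machinery, lysosome, mTORC1 and AMPK signalling, p53 targets, ATF4 targets, endoplasmic reticulum chaperones, sterol and fatty acid synthesis, immediate early and ERK feedback genes, heat shock and oxidative stress, mitosis, S phase, germline stem cell, fibroblast and feeder cell, ovarian somatic cell, oocyte and meiosis, leukocyte and endothelial, histone acetylation enzymes and readers, glycolysis and hypoxia, apoptosis, NF-kappaB targets, interferon response, mitochondrially encoded, haemoglobin and ribosomal protein genes. For each, members that rose and fell were counted with adjustment over all genes and adjusted over the list alone, and 23 lists were tested with camera at a preset correlation of 0.01, adjusted together. The naming rule took, among genes past the threshold with a mean of at least 5 and all 3 C28 libraries beyond all 3 DMSO libraries, the 10 largest rises and 10 largest falls, leaving out predicted genes, clone names, microRNAs, small nucleolar RNAs and pseudogenes; where fewer passed, the next by unadjusted p were added as below the threshold. Each list gave up to 4 members with the smallest p that passed, or 2 as values, in either fit, and Sqstm1, Map1lc3b, Ulk1, Becn1, Tfeb, Ddx4, Dazl and Ifitm3 were always named. Some genes that the rule takes are not reported here.

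Alternatives for the gene counts were a pseudocount of 0.1, no filter, a mean of at least 5, median-ratio scaling, quantile normalization, limma without the trend, library weights, a 2-fold threshold, summed rows, DESeq2 1.42.0 on recovered reads, the replicate block and leaving out each library. Chosen after seeing the data were edgeR 4.0.16 on recovered reads, edgeR and DESeq2 with the block, replicates 2 and 3 alone, and the block with a pair left out, a mean of at least 5, a pseudocount of 0.1 or quantile normalization. Limma, edgeR and DESeq2, each with and without the block, were tested on simulated data for C28 against DMSO with 200 of the genes changed: limma recovered 32% of 1.5-fold, 88% of 2-fold and 100% of 4-fold rises without the block and 88%, 100% and 100% with it, with 0 and 1 false calls among 19054 genes. edgeR recovered 32% of 1.5-fold rises without and 94% with the block among 13360 genes, with 0 and 7 false calls, and DESeq2 56% and 76% among 19054, with 0 and 0. Of genes simulated at a fold of 0.5, limma recovered 74%, edgeR 72% and DESeq2 88% without the block, and 98%, 98% and 92% with it. The simulated data carried a replicate effect shared by same-numbered libraries, with the remaining spread estimated with the block. The gain from the block was thus built in and does not show that the block is right for these data. Changed genes were drawn from abundant genes only, so recovery of low genes was not covered.

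Peak sets were compared by an overlap of at least 1 bp, counted in Python 3.11.15 and checked with bedtools 2.31.1, with 95% Wilson intervals from statsmodels 0.14.6. Alternatives were a -log10 q of at least 10, the same number of top peaks by -log10 q, a reciprocal overlap of 50% and joining peaks within 500 bp; the stricter peaks of a list against all peaks of the other were added after seeing the data. Positions are 1-based in mm9. The planned comparison of promoter peaks with RNA change, and the gene condition in the naming rule for peaks, were not run, since no mm9 annotation was used here and the expression table holds no positions; unshared peaks are therefore named by position alone, on assembled chromosomes.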

Results

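The series compared mouse cells treated for 3 h with C28, a compound known here only by its code name (028 in the sample names), with cells given the solvent DMSO or labelled as control. The cells, of C57BL/6 background, are labelled female germline stem cells (FGSCs), which are mitotic germ cells taken from the ovary and kept in culture. The title of the series concerns autophagy, the delivery of cell contents to the lysosome for breakdown, and its mechanism after C28. RNA sequencing covered 3 DMSO and 3 C28 libraries, and chromatin immunoprecipitation sequencing of H3K27ac, a histone mark of active promoters and enhancers, covered 1 control and 1 C28 library. The RNA libraries held between 16930212 and 19197376 reads assigned to genes, with reads on 19940 to 20302 genes each. RNA encoded by the mitochondrial genome made up 2.78% to 3.26% of these reads. The labels do not say whether the 3 RNA replicates came from separate cultures, so every p-value measures only the spread between these libraries, which may be technical.

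The first question is which cell type markers these libraries carried. Among 26 genes of a germline stem cell list fixed beforehand, 8 averaged 10 or more normalized counts over the 6 libraries, 7 had 0 reads in all 6, and 14 had fewer than 10 reads in total. Ddx4, an RNA helicase of germ cells, was at 0.638 ± 1.10 normalized counts with DMSO and 0.700 ± 0.607 with C28 (SD, n = 3 each). Dazl, an RNA-binding protein of germ cells, had 1 read, in DMSO replicate 2. Pou5f1 and Dppa3 had 0 reads, which allows up to 3 of the 108208382 reads recovered (counting error only). Ifitm3, a membrane protein used as a germline stem cell marker and also made by many other cells, was at 211 ± 114 and 191 ± 92.0 normalized counts. Kit, a receptor of germ cells and of several blood lineages, was the most abundant member, at 22046 ± 1757 and 19928 ± 3115, and Tex14, Etv5, Piwil2, Uchl1, Dnd1 and Zbtb16 also passed an average of 10.

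Markers of other cell types were uneven as well. Ptprc, the pan-leukocyte surface protein CD45, was at 7255 ± 816 normalized counts with DMSO and 7798 ± 969 with C28 (SD, n = 3 each), and Fcer1g, a chain of Fc receptors, at 1381 ± 176 and 1478 ± 185. Other leukocyte members of that list ranged widely: over the 6 libraries Adgre1, a macrophage surface protein, averaged 1348, Cd68 409, Tyrobp 108, Cd52 24.4, Lyz2, a lysozyme, 14.4 and Csf1r, a macrophage receptor, 1.81, and the median of the whole list was 19.4. The endothelial members Kdr, Tek, Tie1 and Emcn each averaged under 1. In the ovarian somatic list, Cyp11a1, the enzyme that opens steroid synthesis, was at 6853 ± 924 and 6788 ± 1007, whereas Foxl2, Inhbb, Cyp19a1 and Hsd3b1 had 0 reads. Of 18 oocyte and meiosis genes, 10 had 0 reads and 2, Sycp1 and Rec8, averaged 10 or more. Fibroblast and feeder cell genes had a median of 47.1 normalized counts, with Col1a1 at 89.2 ± 55.0 and 72.7 ± 29.7 and Vim, made by many cell types, at 26928 ± 2415 and 25811 ± 1406. None of these marker lists was called as shifted between C28 and DMSO in the main fit by camera, limma's test of a gene list against all other genes. The camera adjusted p was 0.447 for the germline, 0.819 for the ovarian somatic, 0.819 for the oocyte, 0.922 for the leukocyte and 0.226 for the fibroblast list. Camera could use 13 of 26, 8 of 16, 3 of 18, 9 of 14 and 19 of 21 members of these lists, so most were tested weakly. The fibroblast list was called down in some alternatives, given below.

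**Figure D1:**
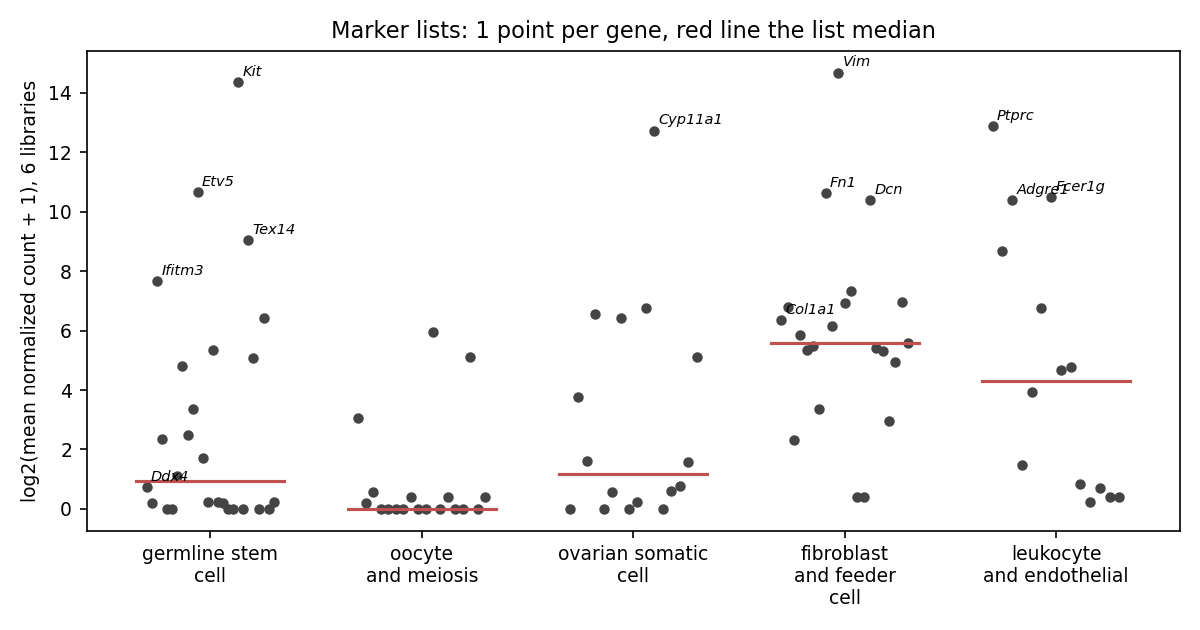
Expression of the 5 cell type marker lists fixed beforehand; each point is a gene, the y axis is log2 of its mean normalized count over the 6 RNA libraries plus 1, and the red line is the list's median. Kit and Ptprc lie high in their lists, and most germline and oocyte genes lie at or near 0.

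The main comparison asks which genes differed between C28 and DMSO after 3 h. Genes of the heat shock response and of antioxidant defence were among those that rose. Hspa1b, an inducible HSP70 chaperone, went from 42.7 ± 8.87 to 679 ± 168 normalized counts (SD, n = 3 each), a 15.4-fold rise with a log2 fold change of 3.95 ± 0.24 (SE). Its near-identical neighbour Hspa1a rose 14.7-fold, from 8.17 ± 5.09 to 129 ± 49.6, and reads may have been split between these 2 copies, so the division between them is uncertain. Hmox1, which breaks down haem, rose 6.14-fold from 1203 ± 175 to 7463 ± 1729. Sstr5, a somatostatin receptor, had the largest fold of the named genes, 18.2, from a low level of 1.58 ± 0.562 to 45.7 ± 8.61. With limma and Benjamini-Hochberg adjustment over 19054 genes, the adjusted p was 0.00416 for Hspa1b, 0.0408 for Hspa1a, 0.00416 for Hmox1 and 0.00881 for Sstr5.

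At an adjusted p under 0.05, limma called 26 genes, of which 23 rose and 3 fell, and 16 changed at least 2-fold. The other genes named for the largest rises were Osgin1, a growth inhibitor induced by oxidative stress (7.47-fold), Trib3, a pseudokinase of the stress response (4.44-fold), Srxn1, which repairs peroxiredoxins (4.25-fold), Chac1, which degrades glutathione (4.2-fold), Slc6a9, a glycine transporter (3.00-fold), and Dnajb4, an HSP40 co-chaperone (2.49-fold). Each of these rises was seen in 3 of 3 same-numbered pairs, which the naming rule fixes in advance. The adjusted p of these genes by limma lay between 0.00416 for Slc6a9 and Dnajb4 and 0.0333 for Chac1.

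Tle3, a transcriptional co-repressor, fell from 1466 ± 136 to 806 ± 61.7 normalized counts (0.551-fold, log2 fold change -0.86 ± 0.10 SE, adjusted p by limma 0.0342). Tcrg-C1, a T cell receptor gamma constant gene from a family of similar genes that may share reads, was at 361 ± 21.7 and 201 ± 6.76 (0.557-fold, adjusted p by limma 0.0439). The third gene that fell, 2900026A02Rik, lies outside the naming rule and is given because so few fell (adjusted p by limma 0.0196). The 8 genes next in line by p were below the threshold: Tlr12 was at 161 ± 18.2 and 68.2 ± 7.25, Lyl1, a blood lineage transcription factor, at 2986 ± 267 and 2004 ± 41.9, Hpdl at 374 ± 51.5 and 195 ± 15.3, and Abi3 at 181 ± 28.9 and 69.9 ± 14.1. The same held for Ccdc102a, Rara, the retinoic acid receptor alpha, Cd3eap and Tmem104, whose C28 to DMSO ratios were 0.668, 0.718, 0.689 and 0.647, and the adjusted p of the 8 ranged from 0.0644 for Tlr12 to 0.136 for Tmem104 in limma.

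Because same-numbered libraries deviated together, the count was also taken with the replicate number as a block. In that fit limma called 914 genes, 485 that rose and 429 that fell, the 26 among them, and 83 of the 914 changed at least 2-fold. The median fold was 1.34 among those that rose and 0.785 among those that fell, so most of the added calls were small changes. All 8 genes below the threshold above fell with the block, with adjusted p from 0.000501 for Lyl1 to 0.00268 for Tmem104. On the recovered reads without the block, DESeq2 called 186 genes, 122 that rose and 64 that fell, and edgeR's quasi-likelihood test called 31. Leaving out a library left 9 genes without DMSO replicate 1, 8 without DMSO replicate 2, 5 without DMSO replicate 3, 8 without C28 replicate 3 and 0 without C28 replicate 2 (1204 at an unadjusted p under 0.05, limma), and with the block 50 genes were called with pair 2 left out and 207 with pair 3 left out.

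**Figure D2:**
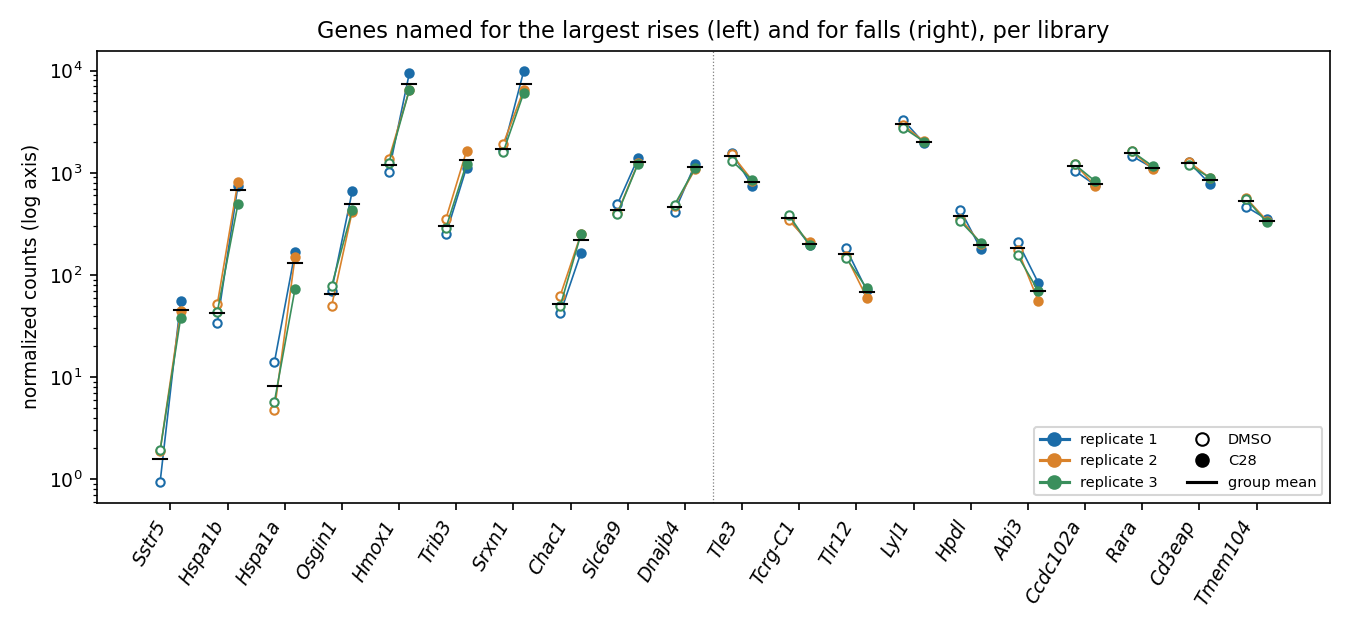
Normalized counts on a log axis for the 10 genes named for the largest rises and the 10 named for falls, with DMSO as open and C28 as filled circles, colours and lines joining same-numbered replicates, and black bars at the group means. Hspa1b rose from a mean of 42.7 to 679 and Tle3 fell from 1466 to 806, while the 8 genes right of Tcrg-C1 did not pass the threshold without the replicate block.

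**Figure D3:**
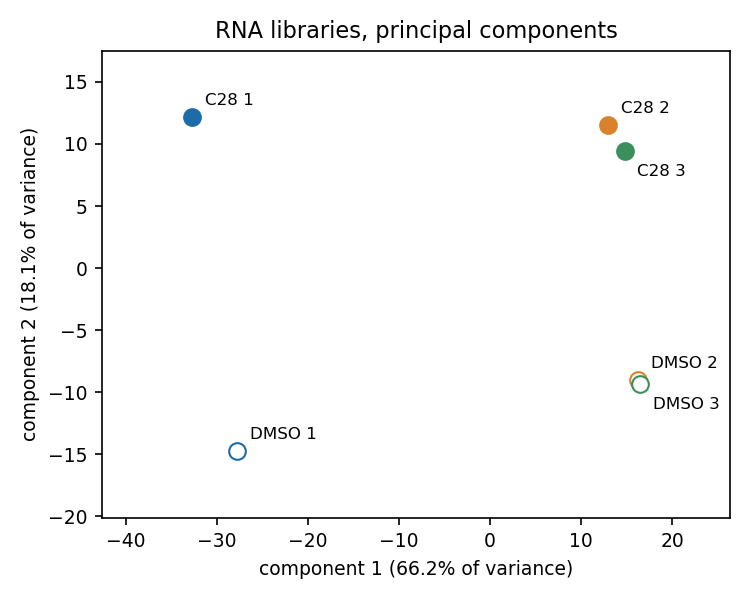
First 2 principal components of the 6 RNA libraries over genes averaging at least 50 normalized counts, with colours for replicate numbers, open circles for DMSO and filled circles for C28. Component 1, with 66.2% of the variance, separates replicate 1 from replicates 2 and 3, and component 2, with 18.1%, separates C28 from DMSO.

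Replicate 1 stood apart in both arms. Between replicate 1 and replicates 2 and 3, 3733 genes differed at an adjusted p under 0.05 in limma, 784 of them at least 2-fold. Of 19 fibroblast and feeder cell genes 11 were lower in replicate 1 and 0 were higher, with a median log2 difference of -0.78, and Col1a1 averaged 38.7 normalized counts in replicate 1 against 102 in the others. Genes of blood and mast cells, chosen after their values were seen, differed both ways: Gzmb, a granule protease, averaged 763 against 69.3 and Il9r, a cytokine receptor, 1218 against 499, while Hdc, which makes histamine, averaged 1.97 against 110, the cytokine Il13 93.1 against 696 and the receptor Il1rl1 1796 against 5119.

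Of the 21 tested members of the heat shock and oxidative stress list, 8 rose, 0 fell and 13 did not pass, with a median log2 fold change of 0.76. Adjusted over the list alone, 16 rose. Hspa1b, Hmox1 and Osgin1 are given above, and Gclc, the catalytic subunit of the enzyme that starts glutathione synthesis, rose 1.75-fold from 2968 ± 66.2 to 5205 ± 77.6 normalized counts. With the replicate block 16 members rose, among them Slc7a11, the cystine importer, from 1625 ± 625 to 5619 ± 1685 (3.55-fold, limma adjusted p 2.02e-07 with the block and 0.172 without). The camera test gave an upward shift with an adjusted p of 7.39e-31, and this was the only list of the 23 tested to keep its call with an estimated correlation (adjusted p = 0.0328 with an estimated correlation). With the block and an estimated correlation no list kept its call (adjusted p = 0.262 for this list).

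The next list held targets of ATF4, the transcription factor of the integrated stress response. Of 26 tested members 4 rose, 0 fell and 22 did not pass, and 12 rose when adjusted over the list alone. Trib3 and Chac1 are given above. Atf4 itself rose 1.78-fold, from 7441 ± 503 to 13293 ± 1660 normalized counts (adjusted p by limma 0.0365), and Sesn2, a stress-induced inhibitor of mTORC1, rose 2.04-fold from 793 ± 69.5 to 1619 ± 128 (adjusted p by limma 0.0109). With the replicate block 19 of the 26 rose. The list shifted up by camera with an adjusted p of 2.85e-20, which missed the threshold with an estimated correlation (adjusted p = 0.0529 with an estimated correlation).

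Autophagy was the process named by the series. Without the block none of the 43 autophagy machinery genes passed in limma, where 7 lay at an unadjusted p under 0.05; 0 rose when adjusted over the list alone, edgeR called 0 and DESeq2 called 2. With the replicate block 5 rose and 0 fell, and adjusted over the list alone 11 rose and 1 fell. Sqstm1, the cargo receptor p62, was at 8159 ± 1924 normalized counts with DMSO and 15246 ± 5404 with C28 (1.83-fold, log2 fold change 0.87 ± 0.25 SE, limma adjusted p 0.413). It was higher in 3 of 3 pairs and rose with the block (SE 0.06, limma adjusted p 2.07e-05). Gabarapl1, an ATG8 protein that coats the autophagosome, was at 777 ± 137 and 1220 ± 140 and rose 1.58-fold with the block, as did Rb1cc1, a subunit of the ULK1 complex (1.26-fold), and Tax1bp1, a cargo receptor (1.13-fold). The camera test gave an upward shift with an adjusted p of 0.0186, lost with an estimated correlation (adjusted p = 0.742 with an estimated correlation) and lost without DMSO replicate 2 (0.061), without DMSO replicate 3 (0.0915) and without C28 replicate 1 (0.449). Fry, another limma test of gene lists, did not call it (fry adjusted p 0.477, and 0.242 with the block).

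Other autophagy genes fixed for naming did not pass in either limma fit when adjusted over all genes. Map1lc3b, the LC3B protein of the autophagosome membrane, was at 1279 ± 56.2 normalized counts with DMSO and 1474 ± 54.3 with C28 (SD, n = 3 each), with limma adjusted p 0.522, and 0.0545 with the block. With the block it was among the members that rose when adjusted over the list alone. Ulk1, the kinase that starts autophagy, was at 437 ± 61.8 and 556 ± 133 (adjusted p 0.756, and 0.162 with the block). Becn1, a subunit of a lipid kinase complex of autophagy, was at 732 ± 75.6 and 734 ± 11.5, a log2 difference of 0.01 with a 95% confidence interval from -0.21 to 0.23. Tfeb, a transcription factor of lysosomal genes, was at 278 ± 57.8 and 254 ± 64.5 (limma adjusted p 0.958, and 0.479 with the block).

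Of 35 lysosome genes 0 passed without the block, with 0 at an unadjusted p under 0.05 in limma and 0 adjusted over the list alone; Lamp2 was at 1921 ± 88.7 and 2172 ± 145 normalized counts and Tfe3 at 349 ± 20.95 and 434 ± 73.0. With the block 1 fell, Gusb, a lysosomal glucuronidase (0.857-fold), also adjusted over the list alone. The camera shift was not called (adjusted p 0.218), except without DMSO replicate 3 (0.0481). In the mTORC1 and AMPK signalling list of 37 genes, Sesn2 alone rose, and 2 rose and 1 fell when adjusted over the list alone. With the block 3 rose, Sesn2, Eif4ebp1, the translation inhibitor 4E-BP1 (1.32-fold), and Ddit4, another mTORC1 inhibitor (1.41-fold), and Prkag2, an AMPK subunit, fell (0.712-fold). Camera gave an adjusted p of 0.922 for that list.

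Among 28 p53 targets, Sesn2 rose without the block, and 9 rose when adjusted over the list alone. With the replicate block 12 rose and 0 fell, including Plk3, a stress kinase (667 ± 20.8 to 1281 ± 251 normalized counts, 1.90-fold), Trp53inp1 (269 ± 27.03 to 568 ± 147, 2.07-fold) and Mdm2, the ubiquitin ligase of p53 (1587 ± 58.8 to 2216 ± 136, 1.40-fold). The list shifted up by camera (adjusted p 2.23e-06), a call lost with an estimated correlation (adjusted p = 0.152 with an estimated correlation). Some lists share genes, so their counts are not separate. Sesn2 is also counted in the ATF4 and mTORC1 lists, and Pmaip1 and Bbc3 are in both the p53 and the apoptosis list. Slc7a11, Ddit4 and Atf3 are in the ATF4 list and also in the heat shock, mTORC1 and immediate early lists, respectively. Of 22 apoptosis genes 0 passed without the block, with 4 at an unadjusted p under 0.05 in limma, 0 by edgeR and 2 by DESeq2, and 3 rose when adjusted over the list alone. With the block 4 rose and 1 fell: the pro-death genes Pmaip1 (1.46-fold), Bbc3 (1.69-fold) and Apaf1 (1.29-fold) rose, and Bcl2l1, which opposes apoptosis, fell (0.861-fold); the camera adjusted p was 0.446.

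Among 20 S phase genes, which serve DNA replication, 0 passed without the block, with 3 at an unadjusted p under 0.05 in limma, 0 adjusted over the list alone, 0 by edgeR and 0 by DESeq2. The median log2 fold change was -0.14 and 1 of the 20 lay above 0. With the block 4 fell, Cdc6 (0.759-fold), Cdt1 (0.812-fold) and Ccne1 (0.829-fold), which license or start replication, and Uhrf1 (0.874-fold), and 11 fell when adjusted over the list alone. Camera called the list down (adjusted p 1.02e-05), but not with an estimated correlation (adjusted p = 0.742 with an estimated correlation). Fry did not call it either (fry adjusted p 0.477, and 0.27 with the block). Ccne2 was at 1543 ± 71.3 and 1315 ± 112 normalized counts. In the mitosis list of 20, Aurkb, a mitotic kinase, fell with the block (0.856-fold), also adjusted over the list alone, and no other member passed; Ccna2 was at 5045 ± 255 and 4517 ± 203. The mitosis list was not called by camera (adjusted p 0.0695), except without DMSO replicate 2 (0.00566) and, with the block, with pair 2 left out (0.0356).

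The immediate early and ERK feedback list held changes both ways. Klf6, a zinc finger transcription factor, rose 2.11-fold from 1274 ± 111 to 2703 ± 369 normalized counts (adjusted p by limma 0.0218), the only call among 36 tested, and 2 rose when adjusted over the list alone. With the block 5 rose and 2 fell, and adjusted over the list alone 8 rose and 7 fell. Fosl1, a FOS family protein (1.61-fold), and Atf3, a stress-induced transcription factor (2.76-fold), rose with the block, and Myc fell (8188 ± 665 to 6616 ± 439, 0.809-fold). Camera gave an adjusted p of 0.819. In the 18 endoplasmic reticulum chaperone genes, Herpud1, of the degradation machinery of that organelle, rose with the block from 1438 ± 123 to 2166 ± 309 (1.499-fold) and was the 1 call adjusted over the list alone; Dnajb9 was at 251 ± 6.39 and 291 ± 4.02. Camera called this list up (adjusted p 0.0380), a call lost with an estimated correlation (adjusted p = 0.742 with an estimated correlation), without DMSO replicate 2 (0.0724), without DMSO replicate 3 (0.0915), without C28 replicate 1 (0.712) and, with the block, with pair 1 left out (0.181). Fry did not call the list (fry adjusted p 0.477, and 0.338 with the block).

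The remaining lists had no call in limma or edgeR without the block, where DESeq2 called 1 member each in the sterol, glycolysis and mitochondrially encoded lists. In the sterol and fatty acid list of 31, Msmo1, an enzyme of sterol synthesis, was at 2107 ± 153 and 2384 ± 242 normalized counts. In the glycolysis and hypoxia list of 19, Vegfa (1.43-fold) and Ndrg1 (1.24-fold) rose and Pfkfb3 fell (0.808-fold) with the block, with 5 rising and 5 falling when adjusted over the list alone. Among 17 NF-kappaB targets, Ptgs2, an enzyme of prostaglandin synthesis, rose with the block (1.48-fold) while Nfkbie (0.730-fold) and Ccl2 (0.662-fold) fell. Of 33 histone acetylation enzymes and readers, Kat2a, an acetyltransferase, fell with the block (0.821-fold), and Kat6b was at 321 ± 17.5 and 397 ± 42.9 and Kdm6b at 726 ± 17.8 and 841 ± 57.1. The camera adjusted p was 0.446 for the sterol, 0.922 for the glycolysis, 0.775 for the histone acetylation and 0.0695 for the NF-kappaB list, the last called down with the block (0.0237) and without C28 replicate 3 (0.00938). With the block that call was lost with pair 1 left out (0.181) and with an estimated correlation (adjusted p = 0.829 with an estimated correlation).

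Interferon response genes had no call with or without the block (15 tested, 3 at an unadjusted p under 0.05 with the block in limma), with Usp18 at 38.5 ± 12.1 and 25.4 ± 5.65 normalized counts; camera gave an adjusted p of 0.260, and 0.0387 without C28 replicate 3. Among 13 mitochondrially encoded genes, ATP6 fell with the block (845 ± 297 to 456 ± 29.3) and ND2 was at 44847 ± 3453 and 47331 ± 2438 (camera adjusted p 0.922). Of 75 ribosomal protein genes, Rpl17 rose with the block (1.51-fold) and Rpl29 was at 94.7 ± 9.95 and 67.0 ± 13.2; both belong to families with many pseudogenes. Camera did not call the ribosomal list (adjusted p 0.226) except without DMSO replicate 1 (0.00027), without C28 replicate 3 (0.0127) and, with the block, with pair 1 left out (5.61e-14). In the marker lists, Pdgfrb, a receptor of fibroblasts, fell with the block (196 ± 124 to 125 ± 73.5), Col3a1 was at 6.34 ± 2.45 and 1.74 ± 1.19, and Fbn1 at 39.9 ± 17.8 and 20.1 ± 7.01; camera called the fibroblast list down without DMSO replicate 1 (0.000263), without C28 replicate 3 (0.0178) and, with the block, with pair 1 left out (0.00382). Id4 was at 3.47 ± 0.538 and 1.05 ± 0.0238, Piwil2 at 76.1 ± 6.49 and 93.8 ± 2.58, Gdf9 at 4.43 ± 3.36 and 10.1 ± 4.88, Sycp1 at 65.7 ± 1.80 and 55.5 ± 5.94, Amhr2 at 0.946 ± 0.952 and 3.13 ± 2.74, and Star at 97.8 ± 14.1 and 115 ± 15.4. Id4, with 14 reads in all libraries together, and Amhr2, with 12, lay near the floor. Each C28 library had 1 read of Id4, so its SD there reflects only the scaling of the libraries. The germline list had 3 members that fell with the block when adjusted over the list alone. Haemoglobin genes had no tested member, with 14 reads in all, on Hba-a1.

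Over the 18 lists in which limma called no member without the block, 30 of 413 tested members lay at an unadjusted p under 0.05, edgeR called 0 and DESeq2 called 8.

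**Figure D4:**
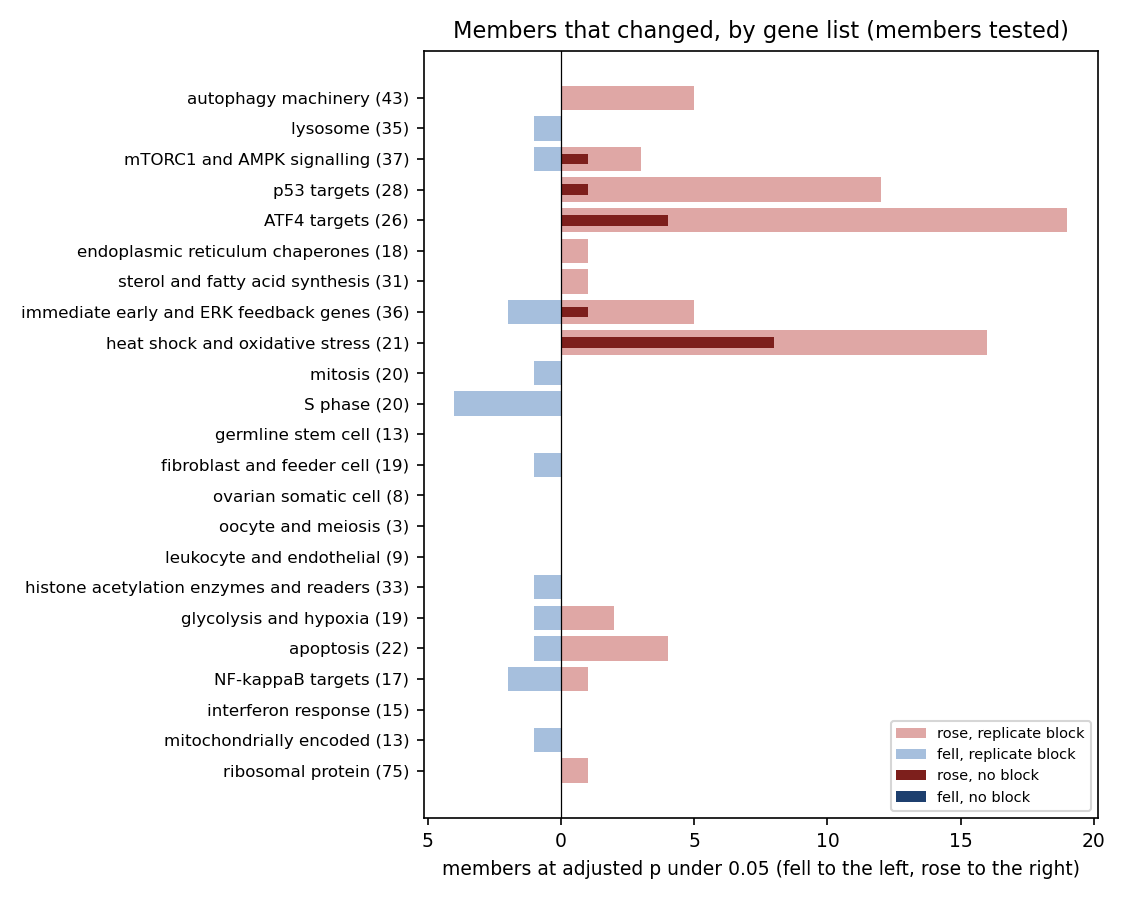
Members that rose (right, red) or fell (left, blue) at an adjusted p under 0.05 in limma, by gene list, with the number of tested members in brackets; dark bars are without and pale bars with the replicate block. The heat shock and oxidative stress list had 8 and 16 rising members and the ATF4 list 4 and 19.

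The authors' deposited table gives its own comparison of C28 with DMSO. Of 12154 genes with an adjusted p there, 186 lay under 0.05, of which 122 rose and 64 fell. Its log2 fold changes, which are shrunken toward 0, were 2.18 for Hspa1b, 1.86 for Hmox1 and 0.53 for Sqstm1, the last with an adjusted p of 0.0138. All 26 genes called by limma without the block were among these 186, and all 186 were among the 914 called with the block.

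The H3K27ac libraries ask where the mark was found after C28 and in control cells. The authors' peak lists held 21776 peaks for C28, covering 19.0 Mb with a median width of 800.5 bp, and 23585 peaks for the control, covering 23.7 Mb with a median width of 931 bp. By an overlap of at least 1 bp, 18196 of the C28 peaks (83.6%, 95% Wilson interval 83.1% to 84.1%) overlapped a control peak, and 17870 of the control peaks (75.8%, 75.2% to 76.3%) overlapped a C28 peak. These intervals cover counting error only. Shared positions made up 15.67 Mb of the 27.02 Mb covered by either list, with 3.34 Mb in C28 peaks alone and 8.01 Mb in control peaks alone. There was 1 library per condition, so the difference between the lists has no replicate check and no test was made. The median fold enrichment was higher in the C28 list (6.11 against 5.55), while the median -log10 q was lower (15.3 against 18.7). Read depth of the 2 libraries was not compared here, so fewer C28 peaks need not mean a loss of the mark.

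Peaks found in a single list were weaker and narrower within their own list, by the authors' own values per peak. The median -log10 q was 5.94 for the 3580 unshared C28 peaks against 19.7 for shared ones, and 6.93 for the 5715 unshared control peaks against 29.1. With each list ranked by -log10 q into 4 groups of equal size, in the strongest group 99.9% of C28 peaks and 99.9% of control peaks overlapped the other list, and in the weakest group 54.4% (53.1% to 55.8%) and 38.6% (37.3% to 39.8%). Of the 13949 C28 peaks with a -log10 q of at least 10, 522 had no control peak of any strength, and of 16253 such control peaks 1451 had no C28 peak. This cut takes no account of a difference in read depth between the libraries. On chromosomes 1 to 19 and X the ratio of C28 to control peak numbers ranged from 0.849 on chromosome 18 to 0.980 on X.

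**Figure D5:**
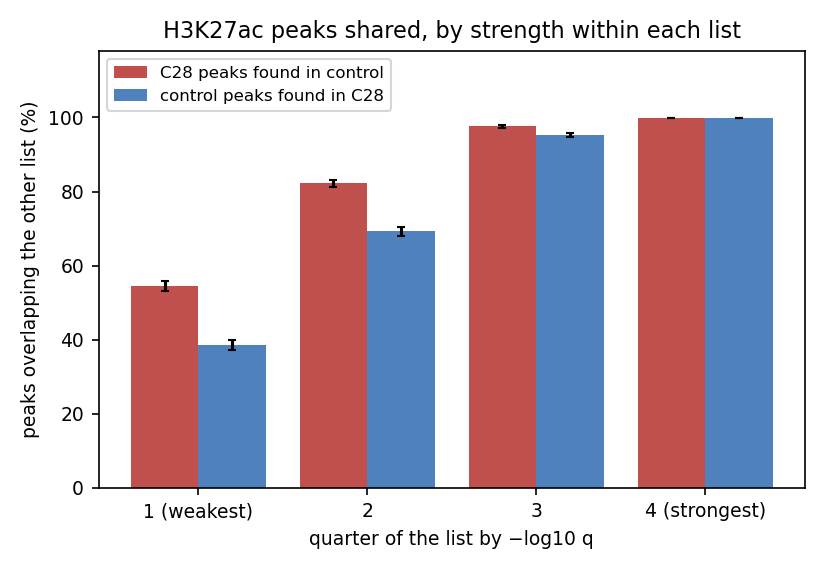
Percentage of H3K27ac peaks that overlap a peak of the other list by at least 1 bp, for 4 groups of equal size in each list, ranked by the authors' -log10 q, with 95% Wilson intervals as error bars. The share rises from 54.4% to 99.9% for C28 peaks and from 38.6% to 99.9% for control peaks.

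The 5 unshared peaks with the highest fold enrichment in each list are given by position in mm9. In the C28 list they lay on chromosome X at 166527217 to 166527507 (31.8-fold), chromosome 2 at 138660693 to 138661014 (13.8-fold), chromosome 10 at 30537518 to 30537907 (12.8-fold), chromosome 17 at 6491990 to 6492288 (12.3-fold) and chromosome 13 at 112490070 to 112490364 (12.3-fold). The control list had them on chromosome 18 at 43135466 to 43135795 (16.9-fold), chromosome 16 at 3114930 to 3115565 (11.8-fold), chromosome 6 at 127058889 to 127059658 (11.7-fold), chromosome 12 at 116980382 to 116981113 (11.4-fold) and chromosome 9 at 100346542 to 100347033 (10.9-fold). No mm9 gene annotation was used here, so these positions were not assigned to genes and peaks were not set against the RNA changes. The unshared C28 peak on chromosome X was 291 bp wide with a -log10 q of 615. It was also among the 5 highest in fold enrichment of the whole C28 list, where the others had a counterpart in the control list. Regions prone to artefact signal were not removed here from either list, so unshared peaks may include such sites.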

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

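Chosen after the results were seen were edgeR, the replicate block fits other than the plain one, the fit of replicates 2 and 3 alone, and the test of stricter peaks against all peaks of the other list. The 26 genes called by limma without a block had the same direction in all 26 other fits. Those fits reuse the same libraries, so the shared direction is no independent support. The number of genes called depended on the fit, and the cause was not tested. Limma without the trend called 51 genes, of which 8 were among the 26, limma with library weights 93, DESeq2 186 and replicates 2 and 3 alone 91, and 16 of the 26 changed at least 2-fold. With the replicate block limma called 914, edgeR 1321 and DESeq2 713. The limma block fit called 1276 with a mean of at least 5, 715 with a pseudocount of 0.1, 269 with quantile normalization, 853 with pair 1 left out, 50 with pair 2 left out and 207 with pair 3 left out. Leaving out a library without the block gave 0 to 23 genes, the 0 without C28 replicate 2 (limma, with 1204 at an unadjusted p under 0.05). With a pseudocount of 0.1, no filter, a mean of at least 5, median-ratio scaling, quantile normalization, summed rows or edgeR without the block the count lay between 20 and 31. Camera called 6 of 23 lists, 4 to 10 when a library was left out, 1 with an estimated correlation and 7 with the replicate block. Fry called 3, the heat shock and oxidative stress, ATF4 and p53 lists, and with the block the same 3. With the block and an estimated correlation camera called 0. In that fit every list had an adjusted p of 0.262 or more. The share of C28 peaks that overlapped a control peak, 83.6%, was 90.2% at a -log10 q of at least 10, 81.2% with the same number of top peaks, 69.0% with a reciprocal overlap of 50% and 96.3% for the stricter peaks against all control peaks. For control peaks, 75.8%, the values were 76.8%, 79.6%, 63.7% and 91.1%, and 76.7% with peaks within 500 bp joined; the cause was not tested, other than that the criteria themselves differ. The alternatives for promoter peaks and RNA change were not run, since that comparison was not made. For the 14 of 26 germline stem cell genes with fewer than 10 reads in total, the depth gives little precision for a comparison of C28 with DMSO.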

Other observations

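Of the tests in this part, the splits with the replicate block, the count of germline genes set against a minor share of other cells, and the 3 tests on replicate 1 were chosen after the result was seen. The genes in the next paragraphs that lie outside the fixed lists were chosen after their values were seen.

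Genes outside the fixed lists are given as examples, without a test of any shared theme. Slc48a1, a haem transporter, went from 2687 ± 202 to 5487 ± 555 normalized counts (SD, n = 3 each) and Mafg, a partner of the transcription factor NRF2, from 1724 ± 141 to 3519 ± 434, both past the threshold without the block (limma adjusted p 0.0109 and 0.0196). Bach1, a repressor of Hmox1, rose with the replicate block from 702 ± 42.1 to 1585 ± 527 (2.18-fold, limma adjusted p 0.00137), and Blvrb, a biliverdin reductase, from 361 ± 66.4 to 665 ± 59.3 (1.86-fold). Procr, the protein C receptor, rose with the block from 34.8 ± 11.6 to 133 ± 25.5. Falls with the block included Cyp1b1, a cytochrome P450 enzyme (563 ± 361 to 213 ± 135, lower in C28 in 3 of 3 pairs), Zfpm1, a cofactor of GATA factors (1553 ± 502 to 884 ± 295), and Ccnd1, cyclin D1 (2784 ± 598 to 1634 ± 570).

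Germ cell markers lay near 0 while blood cell genes were abundant. In a haematopoietic list of 24 genes, none of them in another list, 22 averaged at least 100 normalized counts and 1 had 0 reads, and the list's median lay at the 85.7 percentile of tested genes or above in each of the 6 libraries, which is consistent with RNA mainly from cells of a haematopoietic kind. A minor share of other cells in a culture of germ cells is argued against by a further germline list, where 4 of 24 genes averaged 10 or more and 11 had 0 reads, as far as such cells make these genes. Gata2 (23743 normalized counts on average), Csf2rb (16636) and Cpa3 (6754), genes of blood and mast cells, were chosen after their values were seen, and Fcer1a and Tpsb2, also of mast cells, had 0 reads; also chosen so, Xist, made from the inactive X chromosome of female cells, had 1 read in the 6 libraries together and the Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y had 0. Whether the labelled cells differ from other cultures of that name, or another sample was sequenced, was not tested and stays open.

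Replicate 1 lay apart from replicates 2 and 3 in both arms. A different share of fibroblast feeder cells could lower fibroblast genes, as 11 of 19 were, but 284 genes were at least 2-fold higher in replicate 1, more than a small share would give. A different depth is argued against by the C28 arm, where replicate 1 lay between the others in reads, so that it was outside them in 1 of 2 arms. A different share of mitochondrial RNA was present, with replicate 1 at 3.26% and 3.22% against 2.78% to 3.05% in the other 4 libraries, but it changes other genes by 0.499% at most, far below the 2-fold seen in 784 genes. What that share goes with in the cells, and a different culture, passage or day for replicate 1, were not tested and stay open.

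Antioxidant and heat shock genes rose with C28. A hypothesis is that targets of the transcription factors NRF2 and HSF1 were raised beyond the genes already seen, so a further list was written for each before it was looked at. The NRF2 list shifted up with the replicate block (unadjusted camera p 1.53e-07, and unadjusted p = 0.0299 with an estimated correlation), which may fit such a rise. The HSF1 list did as well (unadjusted camera p 8.41e-06), but unadjusted p = 0.257 with an estimated correlation leaves a rise of HSF1 targets open. The camera p-values of the fixed lists are adjusted together, so the NRF2 value of 0.0299 is not comparable with them. In the same setting the heat shock and oxidative stress list had an adjusted camera p of 0.262 and lost its call. With the block 7 of 17 NRF2 and 5 of 16 HSF1 members rose; without it 0 rose in limma (6 and 5 at an unadjusted p under 0.05) and 0 by edgeR in both lists, and DESeq2 called 3 and 0. Other regulators, and reads shared with pseudogenes of Fth1 and Ftl1, were not tested.

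The number of genes called was set against other splits of the same libraries. Of the 10 splits of the 6 libraries into 3 and 3, 1, the real one, gave as many as 26 genes, and the highest other gave 0. With the replicate block, 1 of the 4 splits that part all 3 pairs, the real one, gave as many as 914, and the highest other gave 0. These splits are too few for a share under 0.05.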
